A study of Mus musculus with 11 samples.

How the data were processed

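RNA was sequenced from whole mouse aortas, taken as arch, thoracic and abdominal parts and cleared of the fat around the vessel, per the labels' protocols. The labels put 11 libraries in 3 groups. WT_CD holds 4 wild-type libraries from mice on chow with 10% of calories from fat. WT_HFD_LNAME holds 4 wild-type libraries and KO_HFD_LNAME 3 Mpst knockout libraries, all from mice on a diet with 45% of calories from fat that also received L-NAME, an inhibitor of nitric oxide (NO) synthases. Per the labels the diet began at 6 to 7 weeks of age and ran for 15 weeks, and the inhibitor was given with the diet for 5 more weeks; for the chow mice the labels state 15 weeks. Nothing in the labels says that each library came from a separate animal, so p-values measure the spread between these samples. RNA was isolated with TRIzol and libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols.

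Read counts per gene were deposited as whole numbers under Entrez gene IDs, without normalization. Per the submitters' processing notes, the authors trimmed reads with Trimmomatic 0.39, aligned them to GRCm38/mm10 with HISAT2 2.2.1 and counted reads per gene with featureCounts 2.0.3. The notes do not state whether the counting used strand, how reads with several alignments were counted, or which annotation was used. Reads from overlapping or antisense genes therefore cannot be told apart, and overlaps are given beside the genes named. The authors also deposited, for KO_HFD_LNAME against WT_HFD_LNAME and for WT_HFD_LNAME against WT_CD, log2 fold changes with their standard error. Both deposited tables also hold a p-value and an adjusted p-value per gene, made with DESeq2 (Galaxy version 2.11.40.7) per the submitters' processing notes; the model, any shrinkage of fold changes and the samples in each fit are not stated.

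The deposited counts were analysed here in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 3 groups, which left 14303 of the 27179 genes in the file; 1319 IDs there had no symbol. Library sizes were scaled with TMM factors, which ran from 0.814 to 1.15. A single model with 1 mean per group was fitted to all 11 libraries with robust glmQLFit, and each comparison was tested with the two-sided glmQLFTest. A gene was called where its Benjamini-Hochberg adjusted p over all tested genes was under 0.05. All adjusted p-values of genes are from this edgeR test unless another tool is named. Standard errors (SE) of log2 fold changes were taken from the F statistic. CPM values, which put counts on a common library size, use the TMM-scaled sizes and are given as mean ± SD, with n = 4 for WT_CD, n = 4 for WT_HFD_LNAME and n = 3 for KO_HFD_LNAME. Plotted values and list scores are log2(CPM + 0.5), a score being the mean over the tested members of a list.

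Gene lists numbered 37 and were fixed with the tests, the rule for naming genes and most alternatives before the data were examined. Of their genes, 934 were found in the file, by symbol or through the GENCODE M21 links from symbols to Entrez IDs, and 2 were not. Lists were tested against all other genes with camera in limma 3.58.1, with the correlation between genes preset at 0.01 and adjustment over the 37 lists, each of which had at least 3 tested members. Beside each list stand the counts of members called higher, lower or not called over all genes, the count adjusted over the list alone, and camera's adjusted p with an estimated correlation. List scores were also compared between groups by exact permutation tests, which were added after the data were seen.

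Named genes are Mpst and, per main comparison, up to 12 higher and 12 lower called genes of largest fold change. These needed a mean CPM of 1 or more in a compared group, no overlap between the libraries of the groups and a symbol that is not a predicted model. For the shorter comparison of KO_HFD_LNAME with WT_CD up to 5 per direction were taken. From each called list, and each list with a called member, the 4 called members with the smallest p were named, or 2 members by smallest p where none was called. Nos3, Cth and Cbs were always named, with Xist, the Y-linked genes, Nnt and Tst as sample checks. Exceptions were chosen after their values were seen: the other Hox genes, Atox1, Lhfpl2, Npas2, Nr1d1, Rn45s, Rn18s and Lars2, the genes called only with another tool or setting, and the genes shared between the comparisons with DESeq2. Where a group held 0 counts of a gene, the fold is a lower bound against 3 counts over the group. Where it held 1 to 3 counts, the ratio is given with a 95% interval. Intervals and floors cover counting error only.

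Total counts per library ran from 8665968 to 15340697, so that 3 counts corresponded to 0.196 to 0.346 CPM. Per library, 16567 to 17905 genes had a count. Positions are from GRCm38.p6, in which 93.0% of the IDs had one. The tests were tried on simulated counts drawn from the real means and library sizes, with 200 changed genes in each of 2 runs per comparison. For WT_HFD_LNAME against WT_CD, 45.2% of the genes changed 2-fold and 93.9% of those changed 4-fold were recovered over 14115 genes, with 4.48% false calls. For KO_HFD_LNAME against WT_HFD_LNAME the shares were 39.2% and 90.4% over 14088 genes, with 4.78% false calls. For KO_HFD_LNAME against WT_CD they were 48.2% and 90.4% over 14055 genes, with 4.53% false calls. The list raised in the simulation was called in 2 of 2 runs of each comparison. Simulated genes were drawn independently, without correlation between genes and without tissue differences between libraries. These shares therefore hold for such counts and do not measure false calls in the real libraries.

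Alternatives were RLE scaling, library size alone, no filter on low counts, a filter of CPM 1 in 3 samples, no robust estimation, limma-voom with quality weights, DESeq2 1.42.0 on all samples or on 2 groups, edgeR on 2 groups, a block for the replicate number, an adipocyte score as covariate, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and leaving out each library. For lists they were an estimated correlation, ranks, limma's fry and lists without members shared between lists. Added after the data were seen were fits without WT_CD 1 and 2, without WT_HFD_LNAME 3 and 4, without Rn45s, Rn18s, Lars2 and mitochondrial genes, and with a cardiac or a B cell score as covariate, and the hydrogen sulfide list without Mpst. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main comparisons. Reads were not available, so neither strand nor the deleted part of Mpst could be examined.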

Results

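Gene expression was measured by RNA sequencing in 11 libraries of aorta from C57BL/6J mice. MPST (mercaptopyruvate sulfurtransferase) is an enzyme that makes hydrogen sulfide and persulfides from 3-mercaptopyruvate. The series asks which vascular genes change in a model of metabolic syndrome, made with a high-fat diet and L-NAME, and what loss of MPST does to vascular gene expression in that model. The 4 WT_CD libraries held 8665968, 11050391, 13136166 and 13300136 counts. The 4 WT_HFD_LNAME libraries held 11562151, 11736662, 13757096 and 12943914 counts, and the 3 KO_HFD_LNAME libraries 11970995, 15340697 and 13214617. Treated here means fed the high-fat diet with L-NAME.

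Mpst (Entrez 246221, chromosome 15, 78406712 to 78414015 in GRCm38.p6) was near the counting floor in each knockout library and present in each wild-type library. The knockout libraries KO_HFD_LNAME 1, 2 and 3 held 3, 5 and 4 counts, which are 0.231, 0.283 and 0.275 CPM. The treated wild-type libraries 1 to 4 held 317, 330, 431 and 377 counts, or 25.7, 31.1, 36.3 and 25.8 CPM. The chow libraries 1 to 4 held 305, 265, 471 and 532 counts, or 36.4, 26.5, 44.1 and 37.2 CPM. The predicted gene Gm52185 overlaps Mpst. Xist, made from the inactive X chromosome, had 0 to 9 counts per library, and Y-linked Ddx3y 53.8 to 147 CPM, so all libraries had the pattern of male tissue. Nnt, which lacks exons in C57BL/6J but not in related substrains, was not called in either main comparison (log2 fold change -0.09, adjusted p = 0.914, and -0.21, adjusted p = 0.952).

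Libraries of the same group differed in tissue and RNA composition. Cardiac muscle markers stood highest in WT_HFD_LNAME 3 and 4, with scores of 5.66 and 6.96, against 1.13 to 3.64 in the other libraries, where WT_CD 3 held the 3.64. The ribosomal precursor Rn45s took 10.1% of counts in WT_CD 1 and 17.4% in WT_CD 2, against 0.815% to 2.98% in the other libraries. The mitochondrial genome gave 7.73% to 27.8% of counts. Erythroid markers scored 6.79 to 7.56 in WT_CD 2, 3 and 4 and 4.52 in WT_CD 1, against 4.88 to 5.99 in the treated libraries. B cell markers scored 4.24 in KO_HFD_LNAME 1 and 3.09 in WT_HFD_LNAME 3, against 0.04 to 2.09 in the others. The first and second principal components held 36.9% and 24.4% of the variance.

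**Figure D1:**
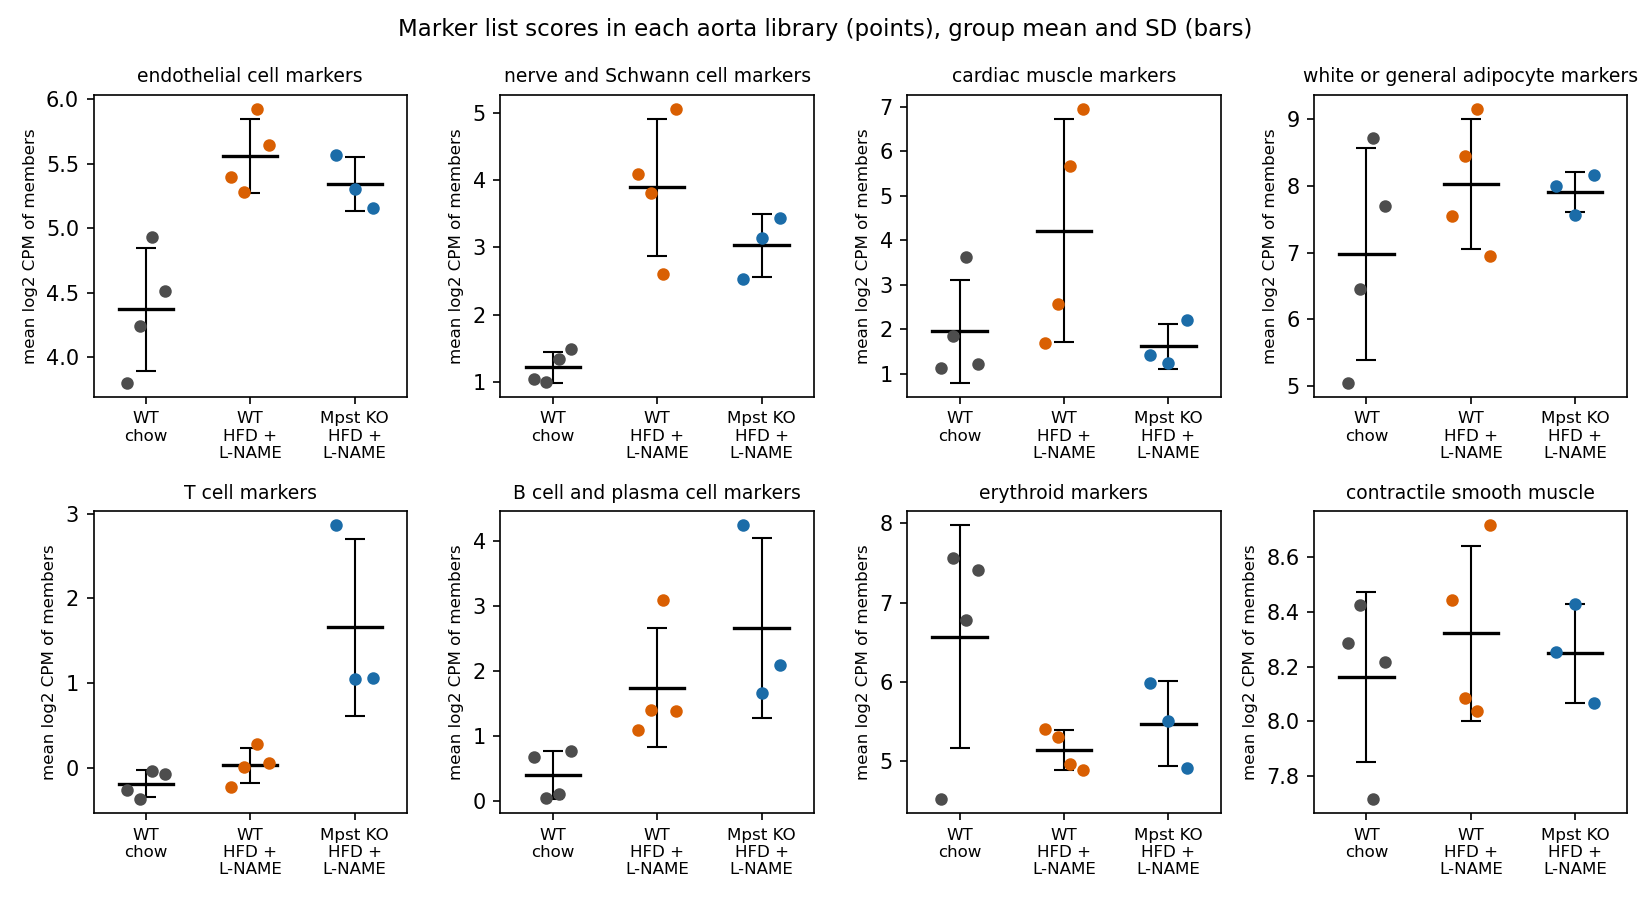
Scores of 8 marker lists in each library, on the vertical axis as the mean log2(CPM + 0.5) of the tested members, with 1 point per library, and bars for each group mean and SD. Endothelial scores lay between 3.80 and 4.93 in chow and between 5.28 and 5.93 in treated wild-type aortas, and T cell scores between 1.04 and 2.87 in knockout aortas.

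The first comparison, WT_HFD_LNAME with WT_CD, asks what the diet with L-NAME changes in wild-type aorta. The catecholamine enzymes Th and Dbh and the co-transmitter Npy, members of the nerve and Schwann cell list, rose in the treated aortas. The nerve and endothelial lists were called up and the erythroid list down with the preset correlation between genes, and none of these calls held with an estimated one (adjusted p = 0.143, 0.143 and 0.546). Genes called higher alone included the transcription factors Sox17 and Sox18, the junction-associated receptor Clec14a and the flow-responsive factor Klf2. Spp1, Bmp2 and Cytl1 of the modulated smooth muscle list, the matrix genes Col8a1 and Thbs1, the adipokine Lep and the immunoglobulin genes Igkc and Ighm also rose. Itih4, an acute-phase protein of plasma, fell, and no member of the erythroid list was called alone. Without WT_CD 1 and 2, the libraries rich in Rn45s, edgeR called 0 genes in this comparison. The groups differed in diet, inhibitor and, as far as the labels tell, in age at collection.

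The 12 called higher genes with the largest folds were the amine enzymes Th and Dbh, the peptide Npy, the granule proteins Scg2 and Pcsk1n, the serotonin receptor Htr3a, the RNA-binding proteins Elavl2 and Celf6, Rit2, Tmem179, Spock3 and Hoxa11. The last is a patterning factor of the posterior body, which overlaps its antisense gene Hoxa11os. Th reached 33.8 ± 29.3 CPM in treated aortas and held 1 count in the chow group, a 1569-fold ratio with an interval of 281 to 62010 (adjusted p = 0.0236). Dbh reached 42.5 ± 36.1 CPM and was 983-fold higher (272 to 8119, adjusted p = 0.0247). Npy rose from 0.316 ± 0.492 to 48.3 ± 41.6 CPM (log2 fold change 6.97, SE 1.22, adjusted p = 0.0286). Pcsk1n rose by 7.12 (SE 1.20, adjusted p = 0.0269; overlapped by Eras) and Htr3a by 7.60 (SE 1.52, adjusted p = 0.0411) on the log2 scale. The ratios were 399-fold (71.2 to 15790) for Rit2, 307-fold (54.7 to 12150) for Tmem179, 267-fold (47.5 to 10560) for Spock3, 182-fold (32.2 to 7201) for Celf6, 175-fold (59.7 to 853) for Scg2 and 129-fold (43.8 to 627) for Elavl2, with adjusted p from 0.0236 to 0.0403. Hoxa11 was at least 33.0-fold higher (2.26 ± 0.875 CPM against 0 counts, adjusted p = 0.0387). The nerve and Schwann cell list rose with a median log2 fold change of 3.40, and 19 of 19 tested members lay above 0. It held 9 members called higher and 10 not called, 16 higher adjusted over the list alone, and had camera adjusted p = 5.9e-25, or adjusted p = 0.143 with an estimated correlation. Its member Stmn2, a growth-cone protein, rose by 3.40 (SE 0.47, adjusted p = 0.0160). Of the 12 gene calls, 0 held without WT_CD 1, 2 or 4 or without WT_HFD_LNAME 1 or 4. Without WT_CD 3, 11 held, without WT_HFD_LNAME 2 or KO_HFD_LNAME 2, 5, and without KO_HFD_LNAME 1, 11. No single library moved the list's median by over 1.5 times.

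**Figure D2:**
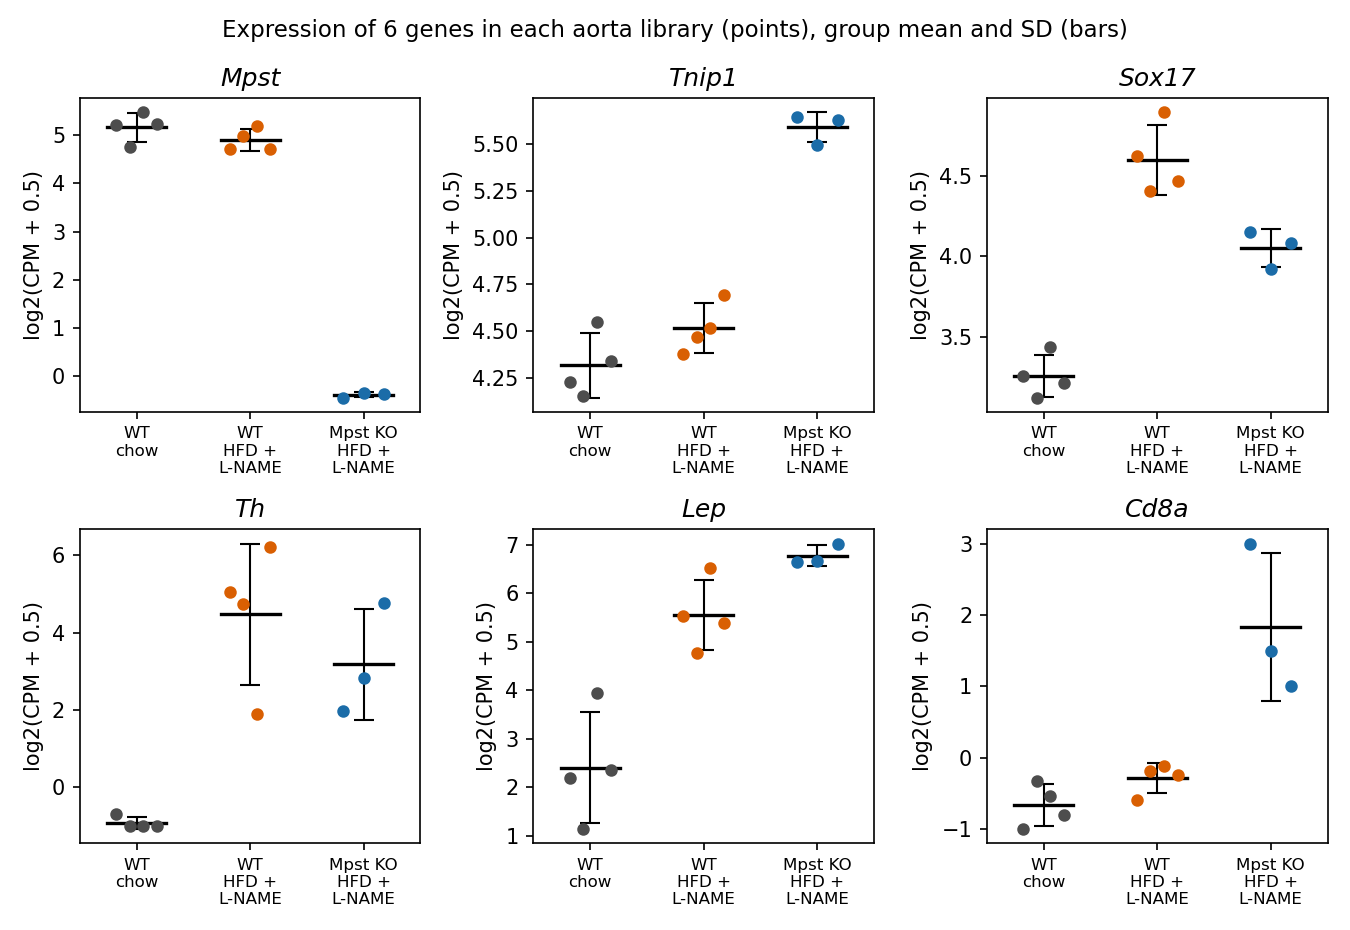
Expression of Mpst, Tnip1, Sox17, Th, Lep and Cd8a in each library, with log2(CPM + 0.5) on the vertical axis, 1 point per library, and bars for each group mean and SD. Mpst CPM was 0.231 to 0.283 in the knockout libraries and 25.7 to 44.1 in the wild-type ones.

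Endothelial cell markers rose by a median of 1.22, with 26 of 26 tested members above 0. Of these 7 were called higher and 19 were not called, and 24 were higher adjusted over the list alone (camera adjusted p = 2.2e-31, adjusted p = 0.143 with an estimated correlation). Sox17, an arterial transcription factor, rose from 9.08 ± 0.888 to 23.9 ± 3.83 CPM (log2 fold change 1.40, SE 0.14, adjusted p = 0.00948). Clec14a went from 12.3 ± 1.11 to 29.6 ± 7.62 CPM, the adhesion molecule Icam2 from 13.5 ± 3.82 to 27.0 ± 5.24 and Sox18 from 20.9 ± 8.99 to 56.4 ± 14.1, with adjusted p of 0.0247, 0.0402 and 0.0453. Nos3, the endothelial NO synthase that L-NAME inhibits, was at 22.3 ± 10.2 CPM on chow and 51.7 ± 10.7 in treated aortas and was not called (log2 fold change 1.20, SE 0.34, adjusted p = 0.110; overlapped by Atg9b). Gch1, a gene of the NO and cGMP list, rose from 2.92 ± 1.12 to 10.5 ± 4.15 CPM (log2 fold change 1.84, SE 0.35, adjusted p = 0.0378). Which cells of the samples hold Gch1 was not tested. The list of Gch1, NO and cGMP signalling, was not called (median 0.03, adjusted p = 0.243), with 1 member higher and 5 higher adjusted over the list alone. Klf2 rose by 0.84 (SE 0.15, adjusted p = 0.0286), in an immediate early list that was not called (median -0.32, adjusted p = 0.340). Sox17 was called without each of the 11 libraries in turn, but not without both WT_CD 1 and 2 (adjusted p = 0.106) or with a cardiac marker score as covariate (adjusted p = 0.0669). Its log2 fold change was 1.33 and 1.32 there and between 1.28 and 1.47 over the alternatives, with adjusted p from 3.4e-14 to 0.106. Clec14a, Icam2, Sox18, Gch1 and Klf2 were lost without WT_CD 2 or 4 or WT_HFD_LNAME 1 or 4. Clec14a also lost its call without WT_CD 1 and Gch1 without WT_CD 1, WT_HFD_LNAME 2 or KO_HFD_LNAME 1 or 2, while Icam2 and Sox18 kept theirs only without WT_CD 3. The endothelial list kept its call, with the preset correlation, without each library in turn.

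Smooth muscle and matrix genes moved in parts. The modulated or osteochondrogenic smooth muscle list rose by a median of 0.32, with 3 members higher and 22 not called, and 7 higher and 1 lower adjusted over the list alone (adjusted p = 0.00147; adjusted p = 0.362 with an estimated correlation). Spp1, which encodes osteopontin, went from 2.03 ± 0.868 to 12.6 ± 5.51 CPM (log2 fold change 2.65, SE 0.47, adjusted p = 0.0302). Cytl1, a cartilage-associated cytokine, rose by 1.38 (adjusted p = 0.0387) and the bone morphogen Bmp2 by 0.78 (adjusted p = 0.0473). Col8a1, a short-chain collagen of the vessel wall, rose from 13.8 ± 3.33 to 43.4 ± 10.1 CPM (log2 fold change 1.66, SE 0.21, adjusted p = 0.0160). Thbs1, a matrix glycoprotein, rose from 10.9 ± 4.82 to 39.7 ± 16.0 (log2 fold change 1.85, SE 0.34, adjusted p = 0.0327). Their list, extracellular matrix and fibrosis, was not called (median -0.11, adjusted p = 0.243), with 2 members higher, and 2 higher and 1 lower adjusted over the list alone. The contractile list was not called either (adjusted p = 0.682) and had a median of -0.17, a mean of 0.18 and an upward test, with 2 members higher and 5 higher adjusted over the list alone. Its called members were Sncg, which encodes gamma-synuclein, at 58.7 ± 11.5 against 192 ± 30.0 CPM (log2 fold change 1.71, SE 0.21, adjusted p = 0.0132), and Pln, the calcium pump regulator phospholamban (log2 fold change 2.86, SE 0.57, adjusted p = 0.0403; overlapped by Cep85l). Pln is also a heart gene and had 47.7 ± 40.4 CPM in treated aortas. The skeletal muscle list was not called (median 0.23, adjusted p = 0.132), with its member Myh1 higher at 39 counts against 1, a 34.2-fold ratio (5.79 to 1384, adjusted p = 0.0288). Without WT_HFD_LNAME 1 the modulated list had a median of 0.17. Of the 18 called members named from lists, apart from Th, Dbh and Npy, 1 held without WT_CD 2 (Sox17), 2 without WT_CD 4, 3 without WT_HFD_LNAME 1 (Sncg, Col8a1, Sox17) and 4 without WT_HFD_LNAME 4. The number was 7 without WT_CD 1, 16 without WT_CD 3, 9 without WT_HFD_LNAME 2, 13 without WT_HFD_LNAME 3, and 10, 6 and 11 without KO_HFD_LNAME 1, 2 and 3.

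Lymphoid, fat, heart and mesothelial transcripts were higher in treated aortas and uneven between libraries. B cell and plasma cell markers had a median of 1.84, with 2 members higher and 11 not called, and 5 higher adjusted over the list alone (adjusted p = 9.9e-05; adjusted p = 0.730 with an estimated correlation). Igkc, the kappa light chain, went from 2.16 ± 1.68 to 47.5 ± 48.0 CPM (log2 fold change 4.41, SE 0.89, adjusted p = 0.0411), and Ighm, the mu heavy chain, from 13.2 ± 4.82 to 103 ± 91.4 (log2 fold change 2.96, adjusted p = 0.0497). Without WT_HFD_LNAME 3 the B cell median was 0.82. White or general adipocyte markers had a median of 0.51, with 1 member higher and 22 not called, and 2 higher adjusted over the list alone (adjusted p = 0.00352; adjusted p = 0.766 with an estimated correlation). Lep, which encodes leptin, rose from 6.29 ± 5.81 to 51.3 ± 28.0 CPM (log2 fold change 3.02, SE 0.57, adjusted p = 0.0371). The adipocyte median was 0.14 without WT_CD 1 and -0.06 without WT_HFD_LNAME 3, both not called, and 0.30, 1.30 and 0.77 without WT_CD 2, WT_CD 3 and WT_HFD_LNAME 4. Without both WT_CD 1 and 2 it was -0.20, not called (adjusted p = 0.490). Brown and beige adipocyte markers had a median of 0.66 with no member called (adjusted p = 0.0159; 0 adjusted over the list alone; adjusted p = 0.766 with an estimated correlation), where glycerol kinase Gk was at 1.44 (adjusted p = 0.145) and Fabp3 at 1.76 (adjusted p = 0.268). That call was lost without WT_CD 1 (0.28), WT_HFD_LNAME 2 (0.42) or WT_HFD_LNAME 3 (0.29), the median was 1.52 without WT_CD 3, and it was -0.02, not called, without both WT_CD 1 and 2. Cardiac muscle markers had a median of 3.60 and no called member, with 11 of 14 higher adjusted over the list alone (adjusted p = 6.3e-05; adjusted p = 0.730 with an estimated correlation), and the median was 2.31 without WT_HFD_LNAME 4. Without both WT_HFD_LNAME 3 and 4, the libraries rich in cardiac transcripts, the cardiac median was -0.30 and not called (adjusted p = 0.936). The troponin Tnnt2 was at 3.06 (adjusted p = 0.0830) and myoglobin Mb at 5.45 (adjusted p = 0.0926). Mesothelial and epithelial markers had a median of 3.29 over 12 members with none called, and 6 higher adjusted over the list alone (adjusted p = 0.00013; adjusted p = 0.730 with an estimated correlation). The mesothelial score was at least 2.40 in WT_HFD_LNAME 2 and 3, -0.00462 and 0.26 in WT_HFD_LNAME 1 and 4 and -0.19 to 0.21 on chow. Upk3b was at 6.03 (adjusted p = 0.104) and Msln at 6.16 (adjusted p = 0.107).

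The renin-angiotensin, aldosterone and endothelin list rose by a median of 0.41 with no member called, and 3 higher adjusted over the list alone (adjusted p = 0.00264; adjusted p = 0.230 with an estimated correlation). The angiotensin receptor gene Agtr1a stood at 1.94 (SE 0.42, adjusted p = 0.050005, not under the threshold) and the aminopeptidase Enpep at 0.57 (adjusted p = 0.119). Interferon-stimulated genes rose by a median of 0.32 with no member called, 0 adjusted over the list alone (adjusted p = 0.0159; adjusted p = 0.766 with an estimated correlation), where Ifi27l2a was at 1.95 (adjusted p = 0.129) and Rsad2 at -1.07 (adjusted p = 0.166). The interferon median was 0.54 without WT_CD 3, and 0.12 without WT_HFD_LNAME 3 and 0.16 without both WT_CD 1 and 2, not called in either case. Mitochondrially encoded transcripts rose by a median of 0.53 with no member called, 0 adjusted over the list alone (adjusted p = 0.0286; adjusted p = 0.766 with an estimated correlation), where COX3 was at 1.23 (adjusted p = 0.208). Their call was lost without WT_CD 2 (0.33), WT_CD 4 (0.36), WT_HFD_LNAME 2 (0.37), WT_HFD_LNAME 3 (0.33) or both WT_CD 1 and 2 (0.27), and the median was 1.10 without WT_CD 3.

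The erythroid list fell by a median of 1.93, with 8 of 8 members below 0, none called and 7 lower adjusted over the list alone (adjusted p = 1.2e-06; adjusted p = 0.546 with an estimated correlation). Its members Alas2, the first enzyme of heme synthesis, and the alpha-globin gene Hba-a2 were at -2.55 (adjusted p = 0.0568) and -2.22 (adjusted p = 0.0890). Slc25a37, a mitochondrial iron importer of erythroid cells, fell from 39.2 ± 17.1 to 14.3 ± 2.58 CPM (log2 fold change -1.46, SE 0.28, adjusted p = 0.0387). Itih4 fell from 211 ± 99.9 to 55.8 ± 10.2 CPM (log2 fold change -1.92, SE 0.29, adjusted p = 0.0232). The other called lower genes that met the naming rule were the olfactory receptor Or2t48 (-1.88), the lymphocyte adaptor Lax1 (-1.39), the mitochondrial carrier Slc25a47 (-0.92), the neuron navigator Nav2 (-0.78), Tmco6 (-0.72; overlapped by Ndufa2), the zinc finger gene Zfp113 (-0.69), Spsb2 (-0.51; overlapped by Tpi1) and the DNA repair gene Xpc (-0.44), with adjusted p from 0.0387 to 0.0487. Of these 10, 0 held without WT_CD 2 or 4 or WT_HFD_LNAME 1 or 4, 2 without WT_CD 1 (Itih4, Slc25a37), 10 without WT_CD 3, 1 without WT_HFD_LNAME 2 or KO_HFD_LNAME 2 (Itih4), 5 without WT_HFD_LNAME 3 or KO_HFD_LNAME 3 and 2 without KO_HFD_LNAME 1.

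The remaining lists were not called in WT_HFD_LNAME against WT_CD. The hydrogen sulfide and sulfur amino acid list had a median of 0.01, a mean of -0.01 and a downward test (adjusted p = 0.876). In it Mpst was at -0.28 (SE 0.16, adjusted p = 0.448), cystathionine gamma-lyase Cth at 0.31 (adjusted p = 0.819), cystathionine beta-synthase Cbs at -0.73 (adjusted p = 0.447) and the sulfurtransferase Tst, the neighbour of Mpst, at 0.16 (adjusted p = 0.930). Medians and adjusted p were 0.62 and 0.0583 for MHC class II, 0.11 and 0.116 for chemokines and cytokines, 0.31 and 0.243 for T cell markers, -0.14 and 0.422 for macrophage markers, and -0.26 and 0.905 for neutrophil markers. They were 0.21 and 0.162 for complement, 0.08 and 0.697 for adventitial fibroblasts, 0.25 and 0.134 for cell cycle, -0.39 and 0.140 for the circadian clock, and -0.08 and 0.193 for ER stress. Metabolic lists gave -0.27 and 0.215 for lipogenesis, 0.27 and 0.232 for fatty acid oxidation, 0.10 and 0.231 for nuclear oxidative phosphorylation, -0.15 and 0.905 for cholesterol, and 0.01 and 0.767 for insulin signalling. NADPH oxidases gave -0.11 and 0.231, antioxidant genes -0.10 and 0.243, neighbours of Mpst 0.16 and 0.548, and the sex and substrain genes -0.13 and 0.239. Adjusted over the list alone, 1 member was called in each of the chemokine, complement and Mpst neighbour lists, and 4 higher and 1 lower in the cholesterol list.

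In this comparison 212 genes were called, 200 higher and 12 lower, and 2161 had an unadjusted p under 0.05 where 715 are expected by chance. The libraries of the groups did not overlap for 7.85% of tested genes, where chance gives 2.86%. Of the 37 lists 12 were called, 11 up and 1 down, and 0 with an estimated correlation. By exact permutation of list scores the endothelial, nerve, B cell, modulated, renin-angiotensin and NO lists reached 0.0286, the smallest p that 4 against 4 libraries can give, and 0.176 after adjustment. With the cardiac covariate the calls of cardiac (-0.14), brown (0.31), white (0.12) and mitochondrially encoded (0.41) lists were lost. With a B cell score as covariate those of B cell (-0.06), brown (0.18), white (-0.06), mitochondrially encoded (0.22) and interferon (0.18) lists were lost, and with an adipocyte score those of brown (-0.11), mitochondrially encoded (0.10) and interferon (0.09) lists. The authors' table called 636 genes, 569 higher and 67 lower, and held 209 of the 212. Npy was not called there (DESeq2 adjusted p = 0.0510). Among the list members named above for this comparison, the authors' table also called some that edgeR did not. Their DESeq2 adjusted p was 0.00141 for Alas2, 0.00324 for Agtr1a, 0.00375 for Tnnt2, 0.0072 for Hba-a2, 0.0225 for Upk3b and 0.0324 for Ifi27l2a. Enpep, Gk, Fabp3, Mb, Msln, Rsad2, COX3 and Nos3 were called in neither. The count was 68, 2, 521 and 3 without WT_CD 1, 2, 3 and 4, and 10, 98 and 21 without WT_HFD_LNAME 1, 2 and 4. Without both WT_CD 1 and 2 edgeR called 0 genes, with 1627 at an unadjusted p under 0.05, and without both WT_HFD_LNAME 3 and 4 it called 59. It called 1 with a cardiac marker score as covariate. Leaving out KO_HFD_LNAME 1 or 2, which enter this comparison through the shared spread estimate and the filter on low counts, gave 110 or 63. The 2 genes left without WT_CD 2 were Sox17 and Lhfpl2, the latter named after its value was seen.

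**Figure D3:**
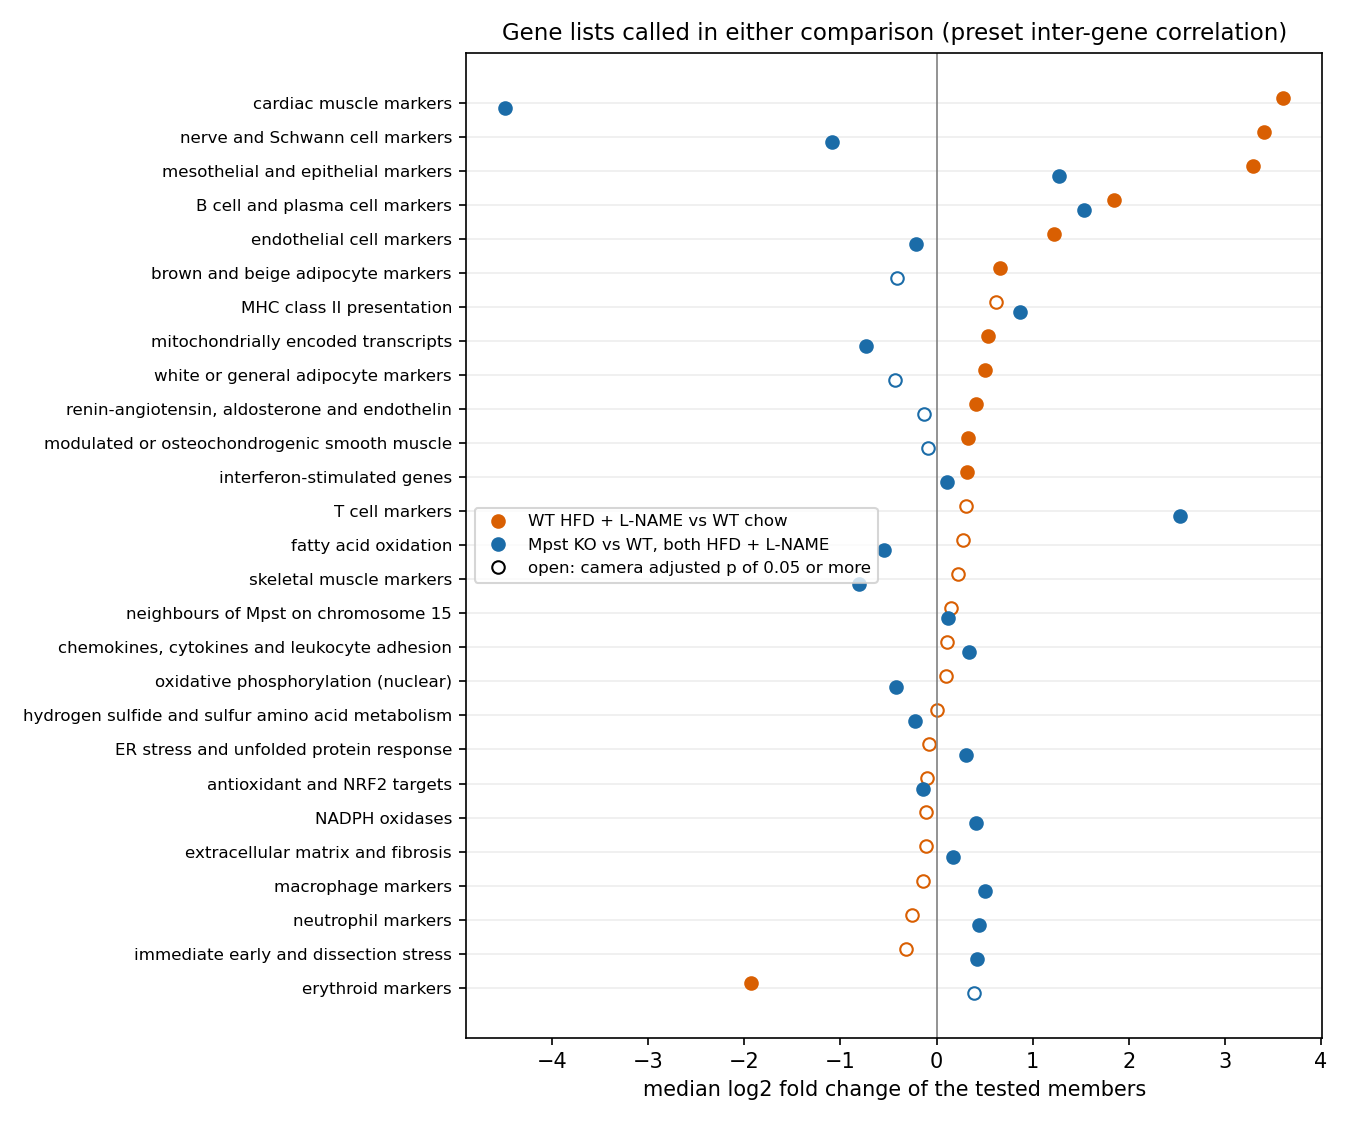
Median log2 fold change of each gene list, on the horizontal axis, for WT_HFD_LNAME against WT_CD and for KO_HFD_LNAME against WT_HFD_LNAME, with 1 point per list and filled points for called lists. The nerve list lay at 3.40 and -1.09, the cardiac list at 3.60 and -4.49, and the T cell list at 0.31 and 2.53.

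The second comparison, KO_HFD_LNAME with WT_HFD_LNAME, asks what loss of Mpst does under the diet and inhibitor. Besides Mpst itself, the single called gene was Tnip1, a partner of the ubiquitin-editing protein TNFAIP3 that restrains NF-kB signalling, and it rose. With the preset correlation between genes, T cell, macrophage, MHC class II and chemokine lists were called up in the knockout aortas and cardiac muscle, mitochondrial and nerve lists down. With an estimated correlation 0 of the 22 called lists held. No member of the lists just named was called alone. The cardiac difference rests on WT_HFD_LNAME 3 and 4, without which the cardiac median was -0.49 and not called (adjusted p = 0.0999).

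Mpst fell from 29.7 ± 5.06 to 0.263 ± 0.0281 CPM (log2 fold change -6.76, SE 0.28, adjusted p = 1.0e-06). Tnip1 (chromosome 11, 54910787 to 54962956) rose from 22.4 ± 2.15 to 47.7 ± 2.64 CPM (log2 fold change 1.08, SE 0.12, adjusted p = 0.0148); the predicted gene Gm12230 overlaps it. Leaving out 1 library at a time left Mpst called each time, while Tnip1 lost its call in 7 of 11. Its adjusted p was 0.187, 0.0810 and 0.166 without KO_HFD_LNAME 1, 2 and 3, 0.115, 0.111 and 0.0924 without WT_HFD_LNAME 1, 2 and 3, and 0.0590 without WT_CD 4. The log2 fold change of Tnip1 lay between 1.03 and 1.25 in all alternatives of this comparison, and its adjusted p between 5.8e-11 and 0.187. Tnip1 was also called between knockout and chow, which joins genotype, diet and inhibitor. There its adjusted p was 0.0122 without WT_CD 2, 0.0206 without WT_CD 4 and 0.00898 without WT_HFD_LNAME 1. It was 0.0169 and 0.0206 without KO_HFD_LNAME 1 and 2, and the call was lost with the B cell covariate. The hydrogen sulfide list fell by a median of 0.23 (adjusted p = 1.9e-07; adjusted p = 0.138 with an estimated correlation), with Mpst as the 1 member lower, 25 not called and 1 lower adjusted over the list alone. The small p rests largely on the deleted gene: without Mpst, a test chosen after the data were seen, the median was -0.23, with 17 of 25 members below 0 (adjusted p = 0.0277; adjusted p = 0.450 with an estimated correlation). With the cardiac covariate the median of the whole list was -0.07. Cth was at -0.64 (adjusted p = 0.950), Cbs at 0.07 (adjusted p = 0.989), Tst at -0.84 (adjusted p = 0.950) and Nos3 at -0.14 (adjusted p = 0.966). Scaling by library size alone moved the median of all genes by 0.169 in this comparison, and beyond that shift no list median changed its sign.

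Immune lists were higher in the knockout aortas by median fold change, but of the lists in this paragraph only T cell and NADPH oxidase scores did not overlap between the genotypes. Macrophage scores were 3.85 to 4.65 in knockout and 3.45 to 4.01 in treated wild-type libraries. MHC class II scores were 4.28 to 5.21 against 3.74 to 4.56, and chemokine scores 3.33 to 3.69 against 2.83 to 3.37. T cell markers rose by a median of 2.53, with 15 of 15 members above 0, none called and 15 higher adjusted over the list alone (adjusted p = 2.1e-32; adjusted p = 0.0847 with an estimated correlation). Cd8a, the co-receptor of cytotoxic T cells, was at 3.79 ± 3.27 against 0.326 ± 0.114 CPM (log2 fold change 3.50, SE 0.66, adjusted p = 0.656), and the T cell receptor gene Trbc2 at 4.88 ± 4.18 against 0.584 ± 0.258 (log2 fold change 3.03, SE 0.62, adjusted p = 0.726). The T cell score was 2.87 in KO_HFD_LNAME 1, 1.04 and 1.06 in the other knockout libraries and -0.23 to 0.27 in treated wild-type aortas, and without KO_HFD_LNAME 1 the median was 1.69. Of the 22 listed T cell genes 15 passed the filter on low counts, while 3 averaged 1 CPM or more in treated wild-type aortas. Members that passed through the knockout libraries alone lie above 0 in part by that filter. Macrophage markers rose by 0.50, with 28 of 28 above 0 (adjusted p = 3.0e-09; 0 adjusted over the list alone; adjusted p = 0.312 with an estimated correlation), and by 0.22 without KO_HFD_LNAME 3. Mpeg1, a pore-forming protein of macrophages, was at 1.19 (SE 0.29, adjusted p = 0.726) and the phagocytic receptor Timd4 at 1.20 (adjusted p = 0.842). MHC class II genes rose by 0.86, with 9 of 9 above 0 (adjusted p = 2.0e-08; 0 adjusted over the list alone; adjusted p = 0.222 with an estimated correlation), H2-DMb1 standing at 0.65 and the protease Ctss at 0.76. Chemokines and cytokines rose by 0.34 (adjusted p = 5.0e-08; 0 adjusted over the list alone; adjusted p = 0.138 with an estimated correlation), with the chemokine Ccl5 at 2.51 and the NF-kB subunit Nfkb2 at 0.49, both with adjusted p = 0.762. NADPH oxidases rose by 0.41 (adjusted p = 0.00017; 0 adjusted over the list alone; adjusted p = 0.0847 with an estimated correlation), with the phagocyte oxidase genes Ncf4 at 1.30 and Rac2 at 1.28. Both Ncf4 and Rac2 are also in the list of neighbours of Mpst on chromosome 15.

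B cell markers rose by a median of 1.54 (adjusted p = 2.4e-05; 0 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation), with Cd37 at 1.36 and Pou2af1 at 1.94. That median was -0.26, not called, without KO_HFD_LNAME 1, 2.35 without KO_HFD_LNAME 2 and 2.41 without WT_HFD_LNAME 3. Neutrophil markers rose by 0.44 over 5 members (adjusted p = 0.0413; 0 adjusted over the list alone; adjusted p = 0.488 with an estimated correlation), with Mmp9 at 1.31 and Csf3r at 0.89. The neutrophil call was lost without WT_HFD_LNAME 1 (0.27) or 4 (0.44), and the median was 0.67 and 0.77 without KO_HFD_LNAME 2 and 3. Interferon-stimulated genes rose by 0.11 (adjusted p = 0.0277; 0 adjusted over the list alone; adjusted p = 0.714 with an estimated correlation), with Ifit3 at -0.54 and Mx1 at 1.08. The interferon call was lost without KO_HFD_LNAME 3 (0.08), WT_HFD_LNAME 2 (0.10) or WT_HFD_LNAME 4 (-0.00126), and the median was 0.0466 and 0.22 without KO_HFD_LNAME 1 and 2 and 0.0661 and 0.43 without WT_HFD_LNAME 1 and 3. The neighbours of Mpst on chromosome 15 rose by 0.12 over 17 members (adjusted p = 0.00662; 0 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation), with Ncf4 and the leukocyte receptor Il2rb (2.10) among them. This was lost without KO_HFD_LNAME 1 (-0.000989) or WT_HFD_LNAME 1 (0.11), and the median was 0.20 without KO_HFD_LNAME 3 and 0.0694 and 0.23 without WT_HFD_LNAME 2 and 3. It was also lost on ranks (adjusted p = 0.0720) and without members shared between lists (adjusted p = 0.134). With a B cell score as covariate the calls of B cell (-0.15), neutrophil (0.40), interferon (-0.00957) and Mpst neighbour (0.08) lists were lost, the neutrophil one also on ranks (adjusted p = 0.0839). ER stress genes rose by 0.30 (adjusted p = 1.8e-07; 1 higher adjusted over the list alone; adjusted p = 0.184 with an estimated correlation), with the chaperones Hyou1 at 0.63 (SE 0.15, adjusted p = 0.726) and Pdia4 at 0.41. Immediate early genes rose by 0.42 (adjusted p = 7.3e-05; 1 higher adjusted over the list alone; adjusted p = 0.301 with an estimated correlation), with Atf3 at 1.31 and Socs3 at 1.03. The ER stress median was 0.18 without KO_HFD_LNAME 3. Mesothelial markers rose by 1.28 (adjusted p = 0.000136; 0 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation), with Krt18 at 0.88 and Krt7 at 1.64, and stood at -0.06, not called, without KO_HFD_LNAME 3. Matrix genes rose by 0.17 (adjusted p = 0.00181; 0 adjusted over the list alone; adjusted p = 0.681 with an estimated correlation), with Col8a1 at -0.83. The matrix call was lost without KO_HFD_LNAME 2 (0.07), WT_HFD_LNAME 3 (0.08) or both WT_HFD_LNAME 3 and 4 (0.13) and with the cardiac covariate (0.03), and the median was 0.28 without KO_HFD_LNAME 1 and 0.26 without WT_HFD_LNAME 1.

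Muscle, mitochondrial, nerve and endothelial lists were lower in the knockout aortas, with 0 members called over all genes, and several of these differences moved with WT_HFD_LNAME 3 and 4, the libraries rich in cardiac transcripts. Without both, medians were -0.49 for cardiac, 0.05 for skeletal, 0.01 for endothelial and -0.05 for antioxidant genes, none of them called. With a cardiac marker score as covariate, the same lists (-0.01, -0.16, 0.05 and 0.02), oxidative phosphorylation (-0.03) and fatty acid oxidation (0.04) lost their calls. Cardiac markers fell by a median of 4.49, with 14 of 14 below 0 and 11 lower adjusted over the list alone (adjusted p = 3.9e-11; adjusted p = 0.278 with an estimated correlation). The calcium pump regulator Sln was at 0.404 ± 0.305 against 57.7 ± 72.7 CPM (log2 fold change -7.14, SE 1.92, adjusted p = 0.726), and troponin Tnnc1 at -4.37 (SE 1.18, adjusted p = 0.726). Skeletal markers fell by 0.80 (adjusted p = 0.000366; 0 adjusted over the list alone; adjusted p = 0.278 with an estimated correlation), with Ckm at -2.97 and Myh1 at -1.77, and by 0.23, not called, without WT_HFD_LNAME 3. Nuclear oxidative phosphorylation genes fell by 0.43, with 76 of 76 below 0 (adjusted p = 3.3e-08; 0 adjusted over the list alone; adjusted p = 0.669 with an estimated correlation). The ATP synthase genes Atp5pf and Atp5mc3 were at -0.39 and -0.38, and the median was -0.27 without KO_HFD_LNAME 2 and -0.22 without WT_HFD_LNAME 3. Mitochondrially encoded transcripts fell by 0.74 (adjusted p = 5.3e-06; 0 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation), with COX3 at -1.64 and ND3 at -2.12, and by 0.45 without WT_HFD_LNAME 3. Fatty acid oxidation genes fell by 0.55, with 27 of 27 below 0 (adjusted p = 0.00185; 0 adjusted over the list alone; adjusted p = 0.681 with an estimated correlation), Eci2 standing at -0.50. That call was lost without KO_HFD_LNAME 2 (-0.35) or WT_HFD_LNAME 3 (-0.20), and the median was -0.35 without WT_HFD_LNAME 2. Nerve markers fell by 1.09, with 18 of 19 below 0 (adjusted p = 7.1e-07; 0 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation), with Stmn2 at -1.15, and by 0.52 without WT_HFD_LNAME 4. Endothelial markers fell by 0.22, with 23 of 26 below 0 (adjusted p = 0.00181; 0 adjusted over the list alone; adjusted p = 0.669 with an estimated correlation), with Sox17 at -0.57 and the phosphatase Ptprb at -0.65. The endothelial call was lost without KO_HFD_LNAME 3 (-0.15) or WT_HFD_LNAME 3 (-0.17), and the median was -0.36 and -0.13 without WT_HFD_LNAME 2 and 4. Antioxidant genes fell by 0.14 (adjusted p = 0.0443; 0 adjusted over the list alone; adjusted p = 0.669 with an estimated correlation), with Gpx3 at -1.34 and Nqo1 at -0.33. This was lost without KO_HFD_LNAME 1 (-0.16) or 2 (-0.13) or WT_HFD_LNAME 2 (-0.12) or 3 (-0.03), and the median was -0.23 without WT_HFD_LNAME 1.

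The other lists were not called between the genotypes. Medians and adjusted p were 0.06 and 0.0719 for complement, 0.39 and 0.163 for erythroid markers, and 0.15 and 0.165 for the clock, where Bmal1 stood at 1.08 and Cry1 at -0.70 and 1 member was higher and 1 lower adjusted over the list alone. They were -0.43 and 0.332 for white adipocyte markers, with Lep at 1.10, -0.41 and 0.171 for brown adipocyte markers, -0.26 and 0.517 for lipogenesis, 0.04 and 0.667 for cholesterol and -0.13 and 0.185 for insulin signalling, with Txnip at -0.56. The renin-angiotensin and endothelin list gave -0.13 and 0.186, with Edn1 at -0.61 and Agtr1a at -1.11. Fibroblast markers gave 0.05 and 0.313, cell cycle 0.05 and 0.318, modulated smooth muscle -0.08 and 0.643, and the sex and substrain genes -0.05 and 0.968. The contractile list had a median of 0.04, a mean of -0.15 and a downward test (adjusted p = 0.874), and the NO list a median of 0.06, a mean of -0.03 and a downward test (adjusted p = 0.968).

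Here 2 genes were called, 1 higher and 1 lower, and 732 had an unadjusted p under 0.05, close to the 715 that chance gives. DESeq2 on all samples called 33 genes, 15 higher and 18 lower, with Cd8a, Trbc2, Lck and Tcf7 higher and Sln and Tnnc1 lower among them. The authors' table called 61, 38 higher and 23 lower, and held both genes. Its DESeq2 adjusted p was 0.00207 for Cd8a and Mpeg1, 0.00348 for Trbc2 and Txnip, 0.0335 for Ctss and 0.0446 for Hyou1 and Socs3. None of these was called by edgeR. The other list members named in the earlier paragraphs on this comparison were not called in the authors' table either. Of the lists 22 were called, 13 up and 9 down, and 0 with an estimated correlation. By exact permutation of list scores T cell, NADPH oxidase and ER stress genes reached 0.0286, the smallest p possible, and 0.352 after adjustment. The count of genes was 1 without each knockout library, without WT_HFD_LNAME 1, 2 or 3 and without WT_CD 4. The groups did not overlap for 7.87% of genes, where chance gives 5.71%.

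The third comparison, KO_HFD_LNAME with WT_CD, joins genotype, diet and inhibitor, since no knockout was on chow. The T cell genes Cd8a, Lck and Tcf7, the macrophage gene Mpeg1, the adhesion molecule Vcam1, the clock factor Bmal1, the glial fatty acid binding protein Fabp7, Igkc and Lep rose. The cytokine signalling inhibitor Socs2, the angiopoietin-like factor Angptl2 and Itih4 fell beside Mpst. Sncg and Sox17 were also called higher, against the same chow libraries as in the first comparison. Tnip1, which the naming rule did not pick here, was called higher too.

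Mpst fell by 7.04 on the log2 scale (SE 0.28, adjusted p = 6.7e-07). Lep went from 6.29 ± 5.81 to 110 ± 17.3 CPM (log2 fold change 4.12, SE 0.61, adjusted p = 0.0304), Lck from 0.404 ± 0.213 to 5.65 ± 4.17 (3.70, adjusted p = 0.0304) and Cd8a from 0.139 ± 0.132 to 3.79 ± 3.27 (4.66, adjusted p = 0.0405). Fabp7 stood at 5.44 (SE 0.88, adjusted p = 0.0413) and Igkc at 5.30 (adjusted p = 0.0483). Bmal1 went from 1.35 ± 0.30 to 5.58 ± 1.39 CPM (log2 fold change 2.03, SE 0.28, adjusted p = 0.0242). Sncg stood at 1.79 (adjusted p = 0.0133), Vcam1 at 0.98 (adjusted p = 0.0440), Mpeg1 at 1.81 (adjusted p = 0.0466), Tcf7 at 3.10 (adjusted p = 0.0483; overlapped by Skp1) and Sox17 at 0.82 (adjusted p = 0.0483). Itih4 fell from 211 ± 99.9 to 42.3 ± 3.35 CPM (log2 fold change -2.32, SE 0.32, adjusted p = 0.0247). Socs2 stood at -1.30 and Angptl2, which Ralgps1 overlaps, at -0.92, both with adjusted p = 0.0475. Nos3 was at 1.06 (adjusted p = 0.233), Cth at -0.33 (adjusted p = 0.843) and Cbs at -0.66 (adjusted p = 0.606). Mpst was the only one of these 15 genes called without each library in turn. Of the 5 highest, 0 held without WT_CD 1, 2 or 4, WT_HFD_LNAME 1 or KO_HFD_LNAME 1 or 2, 1 without WT_HFD_LNAME 2, 2 without WT_HFD_LNAME 4 or KO_HFD_LNAME 3 and 4 without WT_CD 3. Of Itih4, Socs2 and Angptl2, all 3 held without WT_CD 3 or WT_HFD_LNAME 3, Itih4 alone without WT_CD 1 or WT_HFD_LNAME 2 or 4, and none without the others. Of the 6 list members, 0 held without WT_CD 2 or KO_HFD_LNAME 2, Sncg alone without WT_CD 1 or 4, WT_HFD_LNAME 1 or KO_HFD_LNAME 1, 2 without WT_HFD_LNAME 2 or 4, 3 without KO_HFD_LNAME 3 and 5 without WT_CD 3.

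Lists called up by median were mesothelial 4.64 (4.51 with genes near 0 counts at their bound), B cell 3.64, T cell 3.17, nerve 2.25, MHC class II 1.41, endothelial 0.91, Mpst neighbours 0.57, chemokines 0.50, interferon 0.45, macrophage 0.37, cell cycle 0.34, modulated smooth muscle 0.28, complement 0.25, renin-angiotensin 0.25 and ER stress 0.15. Their adjusted p ran from 3.3e-21 for T cell and endothelial markers to 0.0328 for ER stress with the preset correlation. With an estimated correlation 0 of the 20 called lists of this comparison held, the lowest adjusted p being 0.183. White adipocyte markers were called up (adjusted p = 0.0263) with a median of -0.05 and a mean of 0.33. Erythroid markers (-1.52), nuclear oxidative phosphorylation (-0.34), the hydrogen sulfide list (-0.22) and antioxidant genes (-0.22) were called down, with adjusted p of 8.5e-05, 0.00968, 9.4e-05 and 0.00737. Members called over all genes were 3 T cell genes, 1 each in the endothelial, B cell, chemokine, macrophage, modulated and white adipocyte lists, and Mpst in the hydrogen sulfide list. Adjusted over the list alone, 15 T cell, 19 endothelial, 12 nerve, 13 B cell, 10 mesothelial, 8 MHC class II and 6 erythroid members were called, with 4 Mpst neighbours, 3 each of chemokine, modulated and complement genes, 2 white adipocyte genes, 1 each of interferon, macrophage and hydrogen sulfide genes, and 0 in the other called lists. Among lists not called, the NO list had a median of -0.01 and a mean of 0.27, the contractile list a median of -0.12 and a mean of 0.03, and the cholesterol list a median of -0.08 and a mean of -0.09, all with upward tests. Without KO_HFD_LNAME 1 the medians were 2.06 for T cell, 1.70 for B cell and 0.77 for chemokine genes, and the cell cycle (0.12) and Mpst neighbour (0.50) calls were lost. Without KO_HFD_LNAME 2 oxidative phosphorylation (-0.18), renin-angiotensin (0.14) and ER stress (0.15) were lost, and the modulated median was 0.18 and that of white adipocyte markers 0.09. Without KO_HFD_LNAME 3 macrophage (0.06), complement (0.13), ER stress (0.06), renin-angiotensin (0.15) and white adipocyte (-0.11) calls were lost, and the mesothelial median was 2.92. Without WT_CD 1 ER stress (0.15) and white adipocyte (-0.43) calls were lost, and medians were -0.34 for antioxidant, 0.31 for Mpst neighbour, -0.59 for oxidative phosphorylation and 0.49 for renin-angiotensin genes. Without WT_CD 2 complement (0.04), renin-angiotensin (0.15) and white adipocyte (-0.30) calls were lost, and the modulated median was 0.18. Without WT_CD 3 antioxidant (-0.09), cell cycle (0.37) and oxidative phosphorylation (0.16) calls were lost, and medians were 0.25 for ER stress, -0.08 for hydrogen sulfide and 0.99 for white adipocyte genes, the last being 0.03 without WT_CD 4. Without both WT_CD 1 and 2 the calls of renin-angiotensin (0.22), macrophage (0.13), white adipocyte (-0.84), complement (0.07), ER stress (0.17), cell cycle (0.24) and Mpst neighbour (0.33) lists were lost. With a B cell score as covariate those of B cell (-0.06), white adipocyte (-0.67), interferon (0.19), complement (0.15), cell cycle (0.24) and Mpst neighbour (0.09) lists were lost, and with an adipocyte score cell cycle (0.25) and Mpst neighbours (0.22). The hydrogen sulfide call was lost without Mpst (median -0.16, adjusted p = 0.102; adjusted p = 0.543 with an estimated correlation) and on ranks (adjusted p = 0.0658). Scaling by library size alone moved the median of all genes by 0.248 here, and beyond that shift 2 list medians changed their sign, white adipocyte (0.04) and NO (0.00708).

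The third comparison called 45 genes, 41 higher and 4 lower. An unadjusted p under 0.05 was found for 1902 genes, and the groups did not overlap for 13.1%, where chance gives 5.71%. The count was 13, 4, 102 and 5 without WT_CD 1, 2, 3 and 4, 8, 16, 100 and 24 without WT_HFD_LNAME 1, 2, 3 and 4, and 6, 4 and 16 without KO_HFD_LNAME 1, 2 and 3. It was 4 without both WT_CD 1 and 2 and 2 with a B cell marker score as covariate.

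Genes called in both of the first 2 comparisons numbered 0 with edgeR, where independent lists would share 0.0296. DESeq2 on 2 groups gave 11, all with opposite signs, among them the heart genes Mb, Sln and Ckmt2 and the collagen Col8a1. Without WT_CD 3, edgeR gave 1. At an unadjusted p under 0.05 the separate counts were 2161 and 732. Across genes, which are not independent replicates, the log2 fold changes correlated at r = -0.417. Both comparisons share the WT_HFD_LNAME libraries with opposite sign, and simulated unchanged groups gave -0.464 ± 0.0144 over 10 runs. The covariance was -0.163, against -0.0621 ± 0.00277 simulated. With the shared libraries split 2 and 2, r lay between -0.288 and -0.0387 and the covariance between -0.125 and -0.0184. A trait common to the WT_HFD_LNAME libraries still enters both comparisons there, so the splits cannot show a reversal by the knockout.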

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

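Each of the tests of an explanation given here was chosen after the result it bears on was seen. A library counted as far from the others where its gap to the nearest of 4 libraries in its group, as a share of the group's range, passed Dixon's 95% limit. This was so for 13 of 165 groups of values tested, where chance gives about 1 in 20, or 8.25. In 6 of the 13 the group held 1 count of the gene, which sits in a single library by construction, and the other 159 groups gave 7, where chance gives 7.95.

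The genes with 1 count in the chow group were Rit2, Celf6 and Tmem179, at -0.811 in WT_CD 4 on the log2(CPM + 0.5) scale, Th and Myh1 at -0.691 in WT_CD 1, and Spock3 at -0.752 in WT_CD 3. Scg2 was at -0.494 in WT_CD 4, which held its 3 chow counts. Elavl2 was at -0.410 in WT_HFD_LNAME 3, against 3.34 to 3.79 in the other treated wild-type libraries. Slc25a37 was at 3.46 in WT_HFD_LNAME 4, against 3.97 to 4.05, and Socs2 at 5.07 in WT_HFD_LNAME 3, against 5.65 to 5.72. Angptl2 was at 6.67 in WT_CD 3, against 7.10 to 7.16 in the other chow libraries, and Spsb2 at 4.32 in WT_CD 3, against 4.59 to 4.63. The B cell marker score was 3.09 in WT_HFD_LNAME 3, against 1.09 to 1.40 in the other libraries of its group.

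Nerve transcripts rose in treated wild-type aortas, and 4 Hox genes, chosen after their values were seen, rose beside them: Hoxd8 by 2.40, Hoxa10 by 2.81 and Hoxc10 by 3.63 on the log2 scale, and Hoxa11 at least 33.0-fold. The nerve median of 3.08 without WT_CD 1 and 2 argues against the Rn45s-rich chow libraries as the source. A different stretch of aorta in the treated samples may contribute and stays open. Over all 27 tested Hox genes the log2 fold change rose with the paralog number, from the head end to the tail end of the body (Spearman's rho 0.558 across genes, which are not independent, permutation p = 0.00293), but those 4 called genes prompted the test, and without them rho was 0.316 (permutation p = 0.143). Leaving them out also removes every tested paralog above 9, so the second test covers a shorter range of the body. Between the genotypes the same correlation over all 27 genes was -0.754 (permutation p = 1e-05, the smallest that 100000 permutations can give) and 0.468 between knockout and chow (permutation p = 0.0151), in comparisons that share libraries with the first and are not independent of it. The mean log2 CPM of paralogs 9 and above minus that of paralogs 8 and below was -2.39 to -1.31 in knockout libraries, -1.51 to -1.02 in treated wild-type and -4.47 to -2.76 in chow libraries, so the genotypes overlapped. Every chow library lay below every treated library. These means include the 4 called Hox genes, so they cannot decide whether a different stretch of aorta was taken. Attached sympathetic ganglia stay open too: genes of nerve cell bodies lay 2.77 above those of Schwann cells in median log2 fold change (exact permutation p = 0.0327), a set that holds the genes that prompted the question. Without the called genes the difference was 2.12 over 4 and 5 genes (exact permutation p = 0.0952). The nerve list has 11 of its 20 genes at 1 CPM or more on chow and 0 in another list, with Stmn2 at 54.5 and Npy at 48.3 CPM in treated aortas; more innervation, the treatment and age were not tested.

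Endothelial markers rose in treated wild-type aortas, with 25 of the 26 listed genes at 1 CPM or more on chow and 1 also in another list. A lower share of smooth muscle in the treated samples would raise other cell types alike, and the median of adventitial fibroblast markers was 0.0783 against 1.22 for endothelial ones. This argues against a lower share only if clearing the vessels left adventitia alike in both groups, which was not tested. Fibroblast scores ran from 6.32 to 7.24 within the chow group. The endothelial median stayed at 0.834 without WT_CD 1 and 2 and at 0.926 with the adipocyte covariate, which argues against the Rn45s-rich libraries or attached fat as the whole source. Loss of endothelium in handling of chow vessels, a different stretch of aorta, an effect of the treatment and age may each contribute and were not tested for endothelial markers.

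T cell markers were higher in all 3 knockout libraries than in any treated wild-type library. Of the 22 listed genes 1 was at 1 CPM or more on chow and 1 is also in another list, and in knockout aortas Lck reached 5.65 and Trbc2 4.88 CPM. Lymphoid tissue in KO_HFD_LNAME 1 alone could give such a list, but the median without that library was 1.69, which argues against it as the whole source. With the B cell covariate the median was 1.78, which argues only against lymphoid tissue with 1 fixed makeup, since the fit assumes the same relation of T to B cell markers in all libraries. WT_HFD_LNAME 3 scored 3.09 for B cell and 0.27 for T cell markers, and KO_HFD_LNAME 2 scored 1.66 and 1.04. Lymphoid tissue with B cells in varying shares therefore stays open. Lymphoid tissue poor in B cells, the genotype and breeding or housing apart from the wild type stay open and were not tested.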

How the results depend on the processing

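All fits without WT_CD 1 and 2 (Rn45s-rich), without WT_HFD_LNAME 3 and 4 (cardiac-rich), without Rn45s, Rn18s, Lars2 and mitochondrial genes, or with the cardiac or B cell covariate, the hydrogen sulfide list without Mpst, and all counts over other groupings of the samples, were chosen after the data were seen. The other alternatives were planned. Where no reason is given, the cause was not tested. Groups of 3 or 4 libraries that differ in attached tissue limit every count, and at 2-fold the simulated tests found at most 48.2% of changed genes.

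Mpst kept its direction and call in both knockout comparisons in every alternative run, with RLE CPM of at most 0.279 in knockout and at least 25.7 in wild-type libraries. For WT_HFD_LNAME against WT_CD, the 212 genes became 347 with library size alone (198 shared), 138 without a filter (137 shared; more genes tested), 873 with DESeq2 on all samples (all 212 shared), 696 with DESeq2 on 2 groups, 31 with edgeR on 2 groups, 762 with the adipocyte covariate (209 shared), 59 without the cardiac-rich libraries, 1 with the cardiac covariate (Col8a1) and 1 at an adjusted p under 0.01 (Sox17). Without the Rn45s-rich chow libraries 0 were called by edgeR, with 1627 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0880. The share of calls that were higher went from 94.3% to 84.2% with DESeq2 on all samples and 72.2% with the adipocyte covariate. RLE gave 209 (207 shared), the CPM filter 199, voom 174 (103 shared), no robust estimation 240, the B cell covariate 194 (135 shared), genes of ribosomal and mitochondrial RNA left out 259, and a log2 fold change of at least 1 gave 185. Leaving out 1 library gave 2 to 521 genes and 9 to 17 lists. The 12 lists became 0 with an estimated correlation, 19 on ranks and 4 with fry.

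For KO_HFD_LNAME against WT_HFD_LNAME, the 2 genes became 33 with DESeq2 on all samples, 80 with DESeq2 on 2 groups, 7 with the adipocyte covariate (Tnip1, Atox1, Mpst, Mpeg1, Pirb, Usp2 and Iqsec2), and 1, Mpst, with edgeR on 2 groups, without the cardiac-rich libraries, with the B cell covariate and at an adjusted p under 0.01. Leaving out 1 library gave 1 to 3 genes and 18 to 23 lists. The 22 lists became 0 with an estimated correlation and 0 with fry, which asks another question than camera. For KO_HFD_LNAME against WT_CD, the 45 genes became 368 with library size alone, 29 without a filter, 555 and 449 with DESeq2 on all samples and on 2 groups, 148 with voom, 3 with edgeR on 2 groups, 883 with the adipocyte covariate, 4 without the Rn45s-rich libraries (Tnip1, Lhfpl2, Itih4 and Mpst), 2 with the B cell covariate and 4 at an adjusted p under 0.01. Leaving out 1 library gave 4 to 102 genes and 16 to 22 lists, and the 20 lists became 0 with an estimated correlation and 5 with fry. Genes called in both of the first comparisons were 11 with DESeq2 on 2 groups and 0 to 1 leaving out 1 library. The correlation between those comparisons was -0.242, -0.288, -0.0387, -0.109, -0.184 and -0.177 in the 6 splits of the shared libraries. In these splits no library enters both comparisons, but a trait common to the WT_HFD_LNAME libraries still does, with opposite sign. The same correlation was -0.509 to -0.319 leaving out 1 library.

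List medians or tests that changed direction were as follows. Scores used as covariates remove their own list by construction: with the B cell covariate the B cell median was -0.0582, -0.154 and -0.0621 in the 3 comparisons, with the adipocyte covariate the white adipocyte median was -0.293 in the first and -0.341 in the third and the brown median -0.111 in the first, and with the cardiac covariate the cardiac median was -0.138 in the first. The B cell covariate also gave -0.0633 for white adipocyte markers in the first and -0.00957 for interferon genes in the second. Without the Rn45s-rich libraries, brown and white adipocyte medians were -0.0208 and -0.196 in the first and the white one -0.843 in the third. Without the cardiac-rich libraries the cardiac median was -0.303 in the first, and endothelial and skeletal medians were 0.0127 and 0.0469 in the second. The cardiac covariate gave 0.0271 for matrix, 0.0536 for endothelial, 0.0411 for fatty acid oxidation and 0.0156 for antioxidant genes in the second and 0.213 for white adipocyte markers in the third. Leaving out 1 library gave -0.0605 (WT_HFD_LNAME 3) to 1.30 (WT_CD 3) for white adipocyte markers in the first. In the second it gave -0.260 (KO_HFD_LNAME 1) to 2.41 (WT_HFD_LNAME 3) for B cell markers, -0.000989 (KO_HFD_LNAME 1) to 0.228 (WT_HFD_LNAME 3) for Mpst neighbours, -0.0575 (KO_HFD_LNAME 3) to 1.72 (KO_HFD_LNAME 1) for mesothelial markers and -0.00126 (WT_HFD_LNAME 4) to 0.427 (WT_HFD_LNAME 3) for interferon genes. In the third it gave -0.429 (WT_CD 1) to 0.986 (WT_CD 3) for white adipocyte markers, above 0 also without WT_CD 4 or KO_HFD_LNAME 2, and -0.590 (WT_CD 1) to 0.158 (WT_CD 3) for oxidative phosphorylation. Under RLE, the CPM filter and lists without shared members, 12, 12 and 12 of the 12 lists of the first comparison, 22, 22 and 21 of the 22 of the second and 20, 20 and 20 of the 20 of the third held. Without Mpst the hydrogen sulfide list kept its call in the second (adjusted p = 0.0277) and lost it in the third (adjusted p = 0.102), so that 22 and 19 lists were called.

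Replicate numbers do not pair these libraries: of 10 pairs with the same number 4 had r over 0.1 (range -0.226 to 0.586), and 3 of 11 libraries correlated best with their own number. With a replicate block the counts of genes were 42, 1 and 13, the correlation between the first comparisons was -0.336, and the white adipocyte median in the third was 0.40.

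Grouping the same libraries in other ways tells whether chance can be excluded. For the 212 genes between treated and chow wild-type aortas it cannot: 2 of 35 groupings gave as many, and the highest other gave 1422. That grouping set WT_HFD_LNAME 1 and 4 and WT_CD 1 and 2, with white adipocyte scores of 5.05 to 7.55, against libraries with 7.70 to 9.16, which points to a structure of the samples. Fat is not singled out by this. Contractile (8.29 to 8.72 against 7.71 to 8.22), macrophage (3.31 to 3.68 against 3.84 to 4.19) and oxidative phosphorylation scores (6.72 to 7.53 against 7.86 to 8.90) were among others that separated too. So did the hydrogen sulfide score, at 4.55 to 4.65 against 4.74 to 5.07, in wild-type libraries alone. Endothelial and nerve scores overlapped. For the 12 lists it cannot either (30 of 35, highest other 23), nor for the number of genes, 2, and of lists, 22, called between the genotypes (2 of 35 each, highest others 26 and 22), nor for the 20 lists between knockout and chow (15 of 35, highest other 24). A count of calls says nothing about Mpst itself, which held in every alternative run. For the 45 genes between knockout and chow only the real grouping gave as many (1 of 35, highest other 0), the smallest share 35 groupings can give. Taken alone this share lies under 0.05, but 6 counts were tested here without adjustment, so chance is not excluded.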

Other observations

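The list of clock genes was not called in any comparison, and none of its members was called over all genes between the genotypes or between treated and chow wild-type aortas. Bmal1, the activating partner of CLOCK, was called between knockout and chow (adjusted p = 0.0242) and was at 1.35 ± 0.30 CPM on chow, 2.62 ± 0.607 in treated wild-type and 5.58 ± 1.39 in knockout aortas. Npas2, a paralog of CLOCK, was at 3.99 ± 0.205 CPM in knockout and 1.70 ± 0.474 in treated wild-type aortas (log2 fold change 1.22, adjusted p = 0.803), and the repressor Cry1 at 10.8 ± 1.96 against 17.6 ± 2.77 (-0.70, adjusted p = 0.726). Nr1d1, the repressor of Bmal1, was at 135 ± 27.8 against 56.5 ± 29.1 CPM (1.26, adjusted p = 0.886). The labels do not give the time of day at collection. Npas2 and Nr1d1 were chosen after their values were seen.

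Near Tnip1 on chromosome 11, 1 of 19 tested genes within 1 Mb had an unadjusted p under 0.05 between the genotypes, or 5.26%, against 5.12% of all tested genes. That gene was Atox1, a copper chaperone, at -0.90 (SE 0.23, adjusted p = 0.726), chosen after its value was seen. With the adipocyte covariate Atox1 was called, at -0.86 (adjusted p = 0.0157). Gpx3, which ends at 54910387 just before Tnip1, lay above the limit of 0.05, at -1.34 (unadjusted p = 0.0614, adjusted p = 0.950 in the main fit).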
